A study of Mus musculus with 2 samples.

How the data were processed

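Trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of silenced chromatin, was measured by chromatin immunoprecipitation and sequencing in mouse stomach at embryonic day 14.5. Per the labels, the series holds 1 group of 2 biological replicates. Each came from stomachs pooled over male and female embryos of a strain written as B6NTac;B6NCrl/Lap, and the number of embryos of each sex is not stated. Replicate 1 had 1 technical replicate and replicate 2 had 2, which the authors pooled. The labels give a library size range of 300 to 500 without a unit. There is no second tissue, age, mark or treatment, so the comparisons made were between the replicates, between the replicates and the authors' combined lists, and between peaks and the genome's annotation.

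The authors deposited 4 peak lists on assembly mm10, per the notes deposited with them: 1 called on each replicate, 1 called on both replicates' alignments pooled, and 1 of pooled peaks kept as replicated. Every peak of the replicated list was found in the pooled list with equal values when checked. Per the deposited notes, the list of replicate 1 was derived from its own alignments and further files whose kind is not stated, and that of replicate 2 from its own alignments and only 1 of those files; the pooled list used all of them. The aligner, the peak caller, their versions and the threshold for a peak are not given in the sources used here. The deposited lists give for each peak an enrichment value, which is the authors' own ratio for that peak; that it is a fold over a control library is inferred from the peak format and not stated. These folds were used only to describe, rank or filter peaks within a list. The deposited lists also give −log10 p and −log10 q for each peak, in the usual order of the format's columns. The offset of each peak's summit, in bases from its start, was deposited by the authors too and was not used. Read counts were not used here, so the depth of each library is unknown and no interval that needs it is given.

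The lists include weak peaks. The largest q admitted was far above the usual limit: 82.8% of replicate 1 peaks, 63.1% of replicate 2 peaks, 39.9% of pooled peaks and 20.4% of replicated peaks had q over 0.05. A stricter version of each list kept peaks with −log10 q of at least 2.

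Positions were compared with the mm10 reference (GRCm38) and GENCODE mouse release M21, and no peak ended past its chromosome. Comparisons of position used chromosomes 1 to 19, X and Y, and peaks on unplaced and unlocalized scaffolds were set aside from these and counted. Counts, widths, covered bases and q shares of whole lists kept scaffold peaks. So did the comparison of the pooled list with the replicated list. Overlap of peaks needed at least 1 base. Enrichment was tested with a permutation test by rotation: all peaks of a chromosome were moved together by 1 random offset, in coordinates without assembly gaps, which keeps their widths and spacing. P-values were two-sided, from 10000 draws for gene lists and 1000 for the other tests, so the smallest p they can give is 0.0001 or 0.000999. Ratios are the observed share over the mean rotated share. Such a p measures chance placement of 1 list along the genome, not the spread between animals. Benjamini-Hochberg adjustment was made over the 23 gene lists or the 4 feature classes, with a threshold of 0.05. With 2 replicates, means are given with the SD and no test between groups exists.

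Promoters were 1 kb on each side of a transcription start; each base of a peak was counted once, as promoter, exon, intron or intergenic in that order, using protein-coding genes. A gene counted as covered when a replicated peak shared at least 1 base with its body. The 23 lists comprised 5 primary lists (zinc finger, imprinted, olfactory receptor, clustered protocadherin and germline genes) and 18 secondary lists of other clustered families, of control genes and of markers of the cell types and neighbouring organs a stomach sample could hold. For zinc finger genes, a peak over the last exon of the longest coding transcript was compared with one over the promoter of the same gene by an exact two-sided McNemar test. Repeats were the soft-masked bases of the reference, 36.4% of the chromosomes. Sequence uniqueness was judged from 32-base words and their copies on both strands of the assembly, sampled every 50 bases genome-wide.

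Tests, lists, named items and most alternatives were fixed before the data were examined. The items named are the 10 replicated peaks of highest fold, the 10 protein-coding genes with most bases under replicated peaks, up to 4 members of each list by highest fold (or the first 2 members where none had a peak), the 5 longest domains made by joining replicated peaks within 5 kb, and in each replicate the 3 peaks of highest fold that overlapped nothing in the other. A peak was named by the protein-coding gene it overlapped, otherwise by the nearest within 50 kb. Genes named outside this rule were chosen after their values were seen, and the text says so. The alternatives tried were the pooled list, each replicate's list alone, the stricter q, other overlap minimums, peaks matched in number, a 2 kb promoter, genes extended by 5 kb, promoters alone, peaks lying at least 50% inside a gene, and random gene lists matched on length. Added after the data were seen were rotation within single-copy sequence, a replicated list rebuilt from pooled peaks that overlapped both replicates, chromosome densities from each replicate alone, and peaks matched in number by p. Where a ratio passed the threshold neither in the reported setting nor in the alternative, no direction was called for it.

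The rotation test was tested on simulated data: peaks planted in 10%, 25% or 50% of 200 random genes each gave permutation p = 0.00249, the smallest its draws allow, and with no planted peaks p was 0.885. Of 60 lists without planted peaks, between 2 and 4 gave p under 0.05 in those runs. All these lists were 200 genes drawn at random from the autosomes, and the background peaks were the replicated peaks after 1 rotation. The runs therefore do not check the test on clustered families, on smaller lists or where sequence is unevenly unique. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.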

Results

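H3K9me3 marks chromatin kept silent, such as repeats, imprinted alleles and clustered gene families. It was mapped in stomachs of mouse embryos at day 14.5, in 2 biological replicates of 1 group. The list of replicate 1 held 28259 peaks over 7.31 Mb (median width 219 bp), and that of replicate 2 held 11504 peaks over 3.62 Mb (median width 245 bp), a mean of 19882 ± 11848 peaks (SD, n = 2). The pooled alignments gave 19402 peaks over 6.91 Mb, and 10010 of these, over 4.47 Mb, were kept by the authors as replicated. Read depth is unknown for both libraries. All folds below are the authors' own values per peak.

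The replicated H3K9me3 peaks of highest fold lay at transcription factor genes, in a protocadherin cluster and in intergenic sequence, among other places. The replicated peak of highest fold, 12.8, covered the promoter of Gm21887 on chromosome X (170009008 to 170010069), and the overlapping peaks had folds of 12.8 in replicate 1 and 14.9 in replicate 2. It lay at the distal end of X, where the pseudoautosomal region is, among 11 peaks picked because their −log10 p was at least 1.5 times the median of peaks of the same fold (within 5%). The 32-base words of those 11 occurred at a median of 2 places in the assembly. Next came peaks over the body of Klf14, a Krüppel-like transcription factor gene, within 1 kb of its start (chromosome 6, 30956265 to 30958702, fold 10.3), over an internal transcription start of Zfp865 that also lies within Ccdc106 and Gm44973 (chromosome 7, 5028961 to 5032801, fold 9.54), and over the promoter of Tcfl5, a helix-loop-helix transcription factor gene (chromosome 2, 180642670 to 180644309, fold 9.40). The others among the 10 were a Pcdhg peak (chromosome 18, 37755056 to 37759030, fold 7.67), an exonic peak in Zfp157 (chromosome 5, 138455482 to 138457686, fold 7.57), and intergenic peaks. The intergenic ones lay 2138 bp from Zfp988 (chromosome 4, 147335873 to 147336970, fold 8.26), 32308 bp from Epm2a (chromosome 10, 11491953 to 11492351, fold 8.68), and with no protein-coding gene within 50 kb on chromosomes 12 (20232609 to 20234450, fold 9.37) and 16 (3231567 to 3232925, fold 7.67). The chromosome 12 peak had −log10 p raised in the same way, and the chromosome 16 peak lay beside 8 peaks that did. Each of these 10 peaks overlapped a peak in both replicates, but they were taken from the authors' replicated list, so this does not measure how far the replicates agree.

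Across the whole lists, 4045 of 27992 replicate 1 peaks on the chromosomes (14.5%) shared at least 1 base with a replicate 2 peak, against 0.269% on average after rotation (ratio 53.7, permutation p = 0.000999, the smallest the draws can give). Of replicate 2 peaks, 34.2% met a replicate 1 peak. Overlap was highest among the peaks of smallest p, at 45.2% in the first 10% of replicate 1 peaks and 71.8% in the first 10% of replicate 2 peaks. Among peaks with −log10 q of at least 2 in both lists it was 36.8%. Strong unshared peaks existed in both. In replicate 1 the highest were at chromosome 12, 18387117 (fold 6.76) and 114148225 (fold 5.84), and in an intron of A630089N07Rik and B230307C23Rik on chromosome 16 (98010647, fold 5.84). In replicate 2 they lay 17508 bp from Zfp978 (chromosome 4, 147408513, fold 6.41), 17164 bp from Zfp982 (chromosome 4, 147474957, fold 6.06), and at chromosome 16, 7516608 (fold 6.03). Over 4045 overlapping pairs, log2 fold correlated weakly between replicates (Spearman's rho 0.254, Pearson's r 0.340); this is across peaks, which are not independent replicates, and no test was made.

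**Figure D1:**
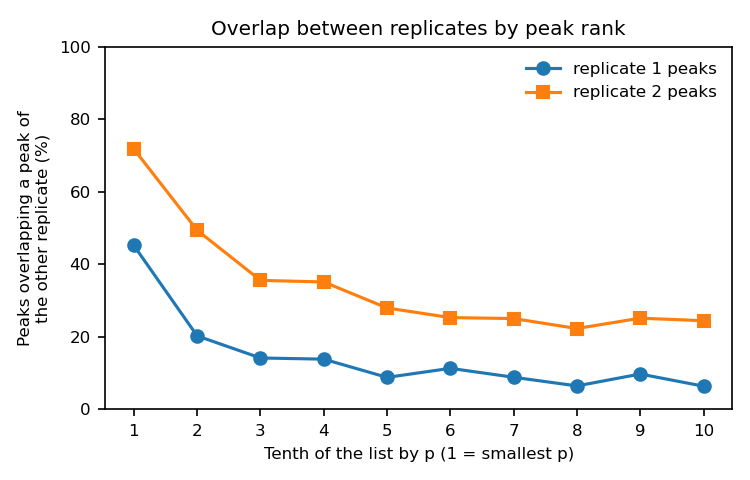
Share of peaks (%) that overlap a peak of the other replicate, in 10 equal groups of each list ranked by p (1 holds the smallest), for replicate 1 (circles) and replicate 2 (squares). Overlap falls from 45.2% to 6.32% in replicate 1 and from 71.8% to 24.4% in replicate 2.

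The authors' replicated list kept 51.6% of pooled peaks, and these were wider (median 349 against 237 bp). It kept 85.2% of pooled peaks with −log10 q of at least 2 and 38.1% of the others. Of the 10010 replicated peaks, 3779 (37.8%) overlapped a peak in both replicates' lists, 2351 in replicate 1 alone, 2670 in replicate 2 alone, and 1210 (12.1%) in neither. Replicated peaks with −log10 q of at least 2 numbered 4727. A list rebuilt from pooled peaks that overlapped each replicate by at least 50% of either peak held 3697, all of them in the authors' list.

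Chromosomes 7, 17 and 18 had the most bases under replicated peaks per Mb and the sex chromosomes the fewest. On chromosome 18, the 1 Mb window from 37000001, which holds the protocadherins, had 107441 of the chromosome's 238127 bp under replicated peaks. Chromosome 7 holds large clusters of zinc finger genes and several imprinted domains, and chromosome 18 the clustered protocadherins. Replicated peaks covered 3190 bp per Mb of ungapped sequence on chromosome 7, 3038 on 17 and 2723 on 18, against 1777 over all autosomes. Chromosome X had 297 bp per Mb, a ratio to the autosomes of 0.167, and Y had 48.0. The X ratio was 0.243 in replicate 1 and 0.169 in replicate 2, and the ratio for chromosome 7 was 1.80 in the replicated list, 1.68 in replicate 1 and 1.72 in replicate 2. No test was made, because peaks on a chromosome are not independent. Single-copy sequence made up 69.7% of X and 4.30% of Y, against 81.0% of all chromosomes. The low density of Y therefore cannot be read as a low level of the mark.

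**Figure D2:**
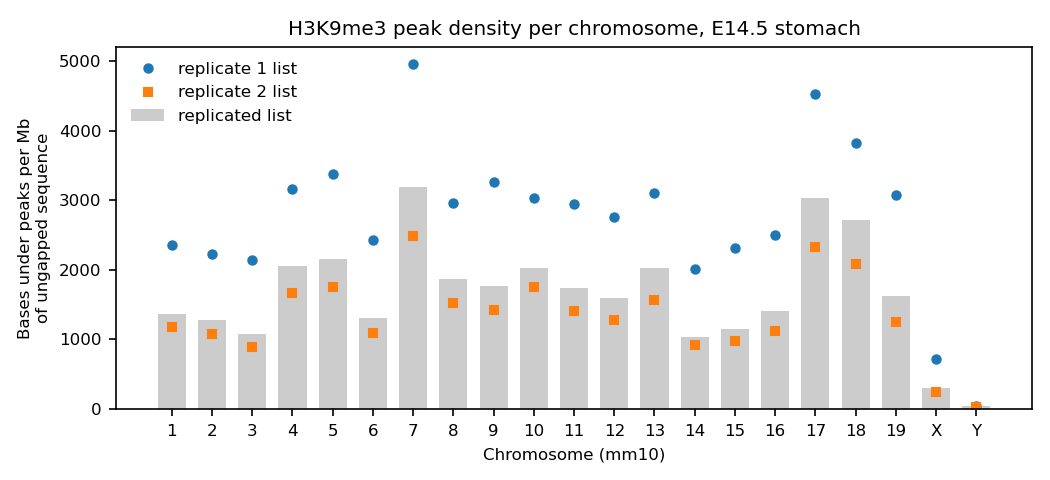
Bases under peaks per Mb of ungapped sequence on each mm10 chromosome, as grey bars for the replicated list, circles for replicate 1 and squares for replicate 2. Chromosome 7 has 3190 bp per Mb and X has 297 in the replicated list, and both replicates place X below every autosome.

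Within genes, bases under replicated peaks favoured exons and promoters over introns. Zinc finger gene bodies held 6.91% of these bases in 0.494% of the ungapped sequence. Whether the preference holds outside zinc finger and protocadherin genes was not tested. Exons held 8.64% of replicated peak bases against 2.87% after rotation (ratio 3.01, adjusted permutation p = 0.00400), and promoters 5.41% against 4.06% (ratio 1.33, adjusted p = 0.00599). Introns held 31.1% against 35.1% (ratio 0.887, adjusted permutation p = 0.0160), while the intergenic share, 54.8% against 57.9%, did not pass the test (ratio 0.946, adjusted p = 0.0869). The promoter call was lost in the pooled list (ratio 1.12, adjusted permutation p = 0.140), and the intron call among peaks with −log10 q of at least 2 (ratio 0.904, adjusted p = 0.140). The intergenic share passed the test instead with that filter (ratio 0.854, adjusted permutation p = 0.00133) and in replicate 2 alone (ratio 0.940, adjusted p = 0.0400). With rotation within single-copy sequence the intergenic ratio of the replicated list was 0.994 (adjusted permutation p = 0.850). That rotation was not run on the filtered list or on replicate 2 alone. The peaks were poor in annotated repeats: 24.0% of their bases were repeat-masked against 33.7% after rotation (permutation p = 0.000999, the smallest the draws can give), and 46.2% were G or C against 42.0% (p = 0.000999). Of the replicated peaks, 99.5% were single-copy by the median copy number of their 32-base words, against 86.2% of the rotated ones. Within single-copy sequence the repeat-masked share was 22.4% against 24.1% after rotation (permutation p = 0.000999). The ratio was thus 0.711 over all sequence but 0.930 within single-copy sequence. The deficit of repeats therefore cannot be read as a low level of the mark in repeats.

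Over all protein-coding genes together, bodies were covered about as often as rotated peaks would cover them, 2185 of 21938 genes (9.96%) against 9.83% (permutation p = 0.598). Zinc finger, imprinted, clustered protocadherin and germline genes were the 4 of 23 lists covered more often than by rotation. In this setting no list was covered less often at adjusted p under 0.05, nor was any at unadjusted p under 0.05 (0 lists). With −log10 q of at least 2, olfactory receptor genes were lower before adjustment only (3 genes, ratio 0.224, permutation p = 0.0460, adjusted p = 0.212).

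Zinc finger genes encode the largest family of mammalian transcription factors, many of which bind transposable elements. Of 424 genes with Zfp, Zscan or Zkscan symbols, 123 (29.0%) carried a replicated peak, against 8.62% after rotation (ratio 3.36, adjusted permutation p = 0.000767, from the smallest p the draws can give). The list of replicate 1 covered 168 of them and that of replicate 2 covered 137, with 116 in both. The members with the highest folds were Zfp865 (fold 9.54), Zfp157 (fold 7.57, with 7 peaks), Zfp777 (chromosome 6, 48023996 to 48025755, fold 7.53) and Zfp873 (chromosome 10, 82058342 to 82062187, fold 7.53, with 13.6 kb of its body covered). Peaks in zinc finger genes lay over the last exon far more often than at the promoter. That exon encodes the zinc finger array in most of them. In all, 95 genes (22.4%) had a peak there and 9 (2.12%) at the promoter. Of the genes with a peak at only 1 of these places, 88 had it at the last exon and 2 at the promoter (exact two-sided McNemar p = 6.62e-24; genes of a cluster are not independent). Among 21514 other protein-coding genes the same counts were 153 and 137 (exact McNemar p = 0.378). Their median last exon was 977 bp against 2238 bp in zinc finger genes, with a 2001 bp promoter window in both. The counts are thus not like for like. In replicate 1 alone the zinc finger counts were 103 and 6 (exact p = 6.62e-24), and with promoters of 2 kb on each side 85 and 4 (exact p = 8.27e-21). The zinc finger ratio was 1.84 in replicate 1 alone, 5.57 with −log10 q of at least 2 and 6.51 in the rebuilt list, and at promoters alone the call was lost (ratio 1.53, adjusted permutation p = 1).

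Imprinted genes are expressed mainly from the maternal or the paternal allele, and the silenced copy often carries repressive marks. Of these, 36 of 53 (67.9%) had a replicated peak, against 14.05% after rotation (ratio 4.84, adjusted permutation p = 0.000767). Several members overlap or adjoin each other and share a peak, as Kcnq1 and Kcnq1ot1 do, so the 36 genes are not 36 separate sites. A peak of fold 6.52 lay over the shared promoter region of Peg3, a zinc finger gene, and Usp29, a ubiquitin protease gene (chromosome 7, 6729189 to 6730814; fold 5.84 in replicate 1 and 5.30 in replicate 2). Impact, a regulator of translation, had a peak over an internal promoter (chromosome 18, 12971954 to 12972325, fold 5.66), and Gnas, which encodes the stimulatory G protein alpha subunit, had 9 peaks, the highest over a promoter (chromosome 2, 174297803 to 174301005, fold 5.51). Promoters alone were covered in 30.2% of the list against 1.01% after rotation (ratio 29.8, adjusted permutation p = 0.00115). The list's ratio was 2.39 in replicate 1 alone and 8.84 in the rebuilt list. Among members chosen after their values were seen, Cdkn1c, a cell cycle inhibitor gene (fold 5.22), Plagl1 (5.15), Kcnq1ot1, an antisense RNA (4.68), Nnat (4.65) and Peg10 (4.50) also carried peaks, whereas the bodies of H19, Igf2, Dlk1 and Dio3 carried no replicated peak.

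The clustered protocadherins, cell surface proteins of neurons, held the longest domain of replicated peaks joined within 5 kb on the chromosomes. Of 57 genes, 47 (82.5%) carried a replicated peak, against 20.5% after rotation (ratio 4.03, adjusted permutation p = 0.000767). The domain ran over the Pcdhga and Pcdhgb genes (chromosome 18, 37656698 to 37774294, 118 kb) with 77 peaks that covered 65.3% of it. Each of the 18 annotated Pcdhga and Pcdhgb first exons in it, every one of which has its own promoter, held a peak, and a median of 92.7% of the exon was covered. The 10 protein-coding genes with most bases under peaks were all models of this locus: 3 read-through models (Gm42416 with 112 kb, Gm37013 and Gm37388), Pcdhga1 (74.9 kb), Pcdhga2 (72.2 kb), Pcdhga3 (69.3 kb), Pcdhgb1 (65.5 kb), Pcdhga4 (62.3 kb), Pcdhgb2 (58.5 kb) and Pcdhga5 (56 kb). These models share their 3' exons and overlap, so a peak counts for several genes, including the peak of fold 7.67 that lies in Pcdhga1, Pcdhga2, Pcdhga10 and Pcdhga11. Taken alone in a comparison chosen after the data were seen, the 12 Pcdhga and the 12 Pcdha genes, all with peaks, did not pass (permutation p = 0.204 and 0.369 before adjustment). All 12 is the largest count possible, and overlapping models are hit together under rotation, so neither family could have passed. A second domain covered the Pcdha genes (chromosome 18, 36988863 to 37026496, 15 peaks). The list's ratio was 2.13 in replicate 1 alone and 8.48 in the rebuilt list.

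**Figure D3:**
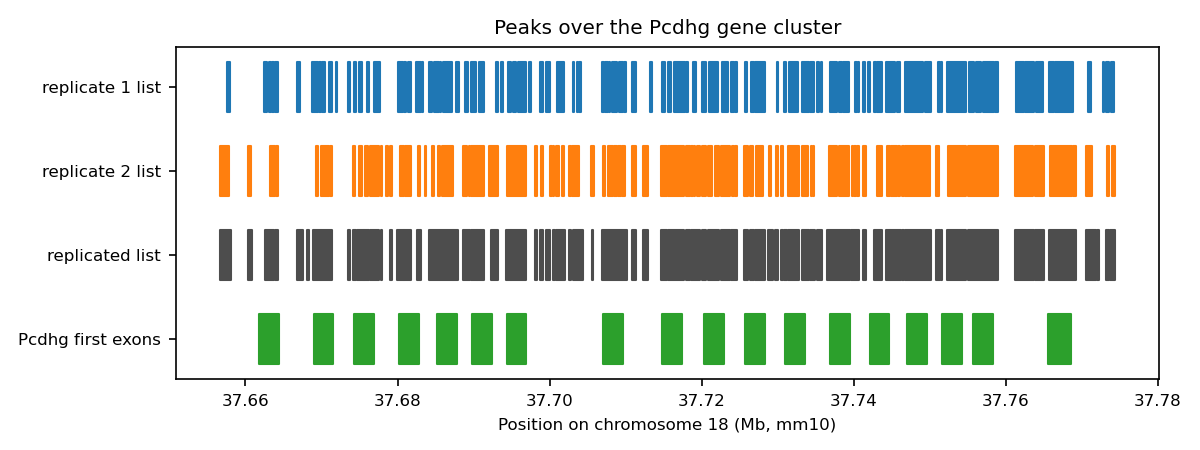
Peaks over the Pcdhga and Pcdhgb genes on chromosome 18 (position in Mb, mm10), drawn to scale for the replicate 1, replicate 2 and replicated lists above the 18 first exons. Every first exon carries replicated peaks, and a median of 92.7% of its bases is covered.

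Some germline genes, which act in meiosis and germ cell development, carried H3K9me3, mostly at their promoters. Of 40 genes, 11 (27.5%) had a replicated peak, against 8.28% after rotation (ratio 3.32, adjusted permutation p = 0.00115). The highest folds were at Dazl, an RNA-binding protein of germ cells (chromosome 17, 50293209 to 50294042, fold 4.90), Ddx4, a germ cell RNA helicase (chromosome 13, 112651989 to 112652637, fold 4.88), Smc1b, a meiotic cohesin (chromosome 15, 85131482 to 85131756, fold 4.36), and Meioc, a meiotic regulator (chromosome 11, 102665049 to 102666476, fold 4.22). Promoters alone were covered in 22.5% of the list against 0.799% after rotation (ratio 28.2, adjusted permutation p = 0.00115). For body overlap the call rested on replicate 2: in replicate 1 alone the ratio was 1.29 (adjusted permutation p = 0.750). Of the 11 genes, Smc1b and, named after their values were seen, Tdrd1, Sycp2, Taf9b and Stag3 had no peak in replicate 1. In the rebuilt list the ratio was 3.86 with adjusted permutation p = 0.0535.

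Other clustered families did not pass the test. Olfactory receptor genes had peaks in 15 of 1135 (1.32% against 2.51%, ratio 0.527, adjusted permutation p = 0.417), with the highest folds in Olfr137 (4.07), Olfr1440 (3.62), Olfr1418 (3.21) and Olfr348 (3.21). Vomeronasal receptor genes, pheromone receptors clustered on chromosomes 7 and 17 among others, had peaks in 30 of 329 (9.12% against 6.08%, ratio 1.5, adjusted permutation p = 0.417), led by Vmn1r70, Vmn2r94, Vmn2r93 and Vmn2r102 (folds 4.07 to 4.36). Against length-matched random gene lists the vomeronasal ratio was 1.85 with adjusted permutation p = 0.00322. Those lists were drawn gene by gene and do not keep clusters, so that p treats clustered genes as independent. Cytochrome P450 genes had peaks in 8 of 94 (ratio 0.977, adjusted permutation p = 1), in Cyp39a1 (fold 4.50), Cyp3a16, Cyp3a57 and Cyp2c29 among them. No replicated peak lay in any of the 61 serpin genes (such as Serpine2 and Serpinb5), 42 beta-defensin genes (Defb18, Defb41) or 49 keratin genes (Krt222, Krt24). The adjusted p for these 3 lists ranged from 0.417 to 0.871. In replicate 1 alone peaks lay in 65 olfactory receptor genes (ratio 0.812), 64 vomeronasal receptor genes (ratio 1.25), 24 cytochrome P450 genes (ratio 1.12), 7 serpin genes (ratio 0.766), 2 beta-defensin genes (ratio 1.06) and 2 keratin genes (ratio 0.570), and none of these lists passed the test there.

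Coverage of genes used by the stomach itself passed the test neither in the replicated list nor in either replicate alone. Of 34 stomach epithelium genes only Muc5ac, a gastric mucin gene, had any (an exonic peak at chromosome 7, 141797457 to 141798296, fold 3.37), and of 31 mesenchyme genes only Pdgfrb did (fold 2.78). These shares were 2.94% against 7.41% after rotation (ratio 0.397) and 3.23% against 6.5% (ratio 0.496). In replicate 1 alone 10 epithelium genes (29.4%, ratio 1.5) and 7 mesenchyme genes (22.6%, ratio 1.27) had peaks. Enteric neuron and glia genes had peaks in 2 of 19 (Chat, fold 3.95, and Gfra1, fold 3.43), and blood and endothelium genes in 2 of 26 (Tek, fold 3.50, and Flt1, fold 3.35). Among genes of other organs, liver genes had 3 of 24 (Cps1, fold 3.93, Hpd and Cyp3a11), central nervous system genes 1 of 24 (Slc17a7, a vesicular glutamate transporter, fold 4.16), and striated muscle genes 4 of 24 (Ttn, fold 4.50, Myh8, Ryr1 and Ryr2). Pluripotency genes had 2 of 19 (Zfp42, fold 3.64, and Esrrb, fold 3.21), and genes of the heterochromatin machinery 2 of 27 (Smchd1, fold 4.42, and Atf7ip, fold 4.36). Hox cluster genes (39, such as Hoxd13 and Hoxd12), replication-dependent histone genes (67, Hist2h2ab and Hist2h2ac), ribosomal protein genes (79, Rpl7 and Rpl31) and housekeeping genes (30, Actb and Gapdh) had none. None of these 13 lists passed the test (adjusted permutation p from 0.677 to 1), and for each of the lists without a peak 0 lay inside the central 95% of rotated shares, so a lower share could not have been detected. In replicate 1 alone peaks also lay in 6 enteric, 6 blood and endothelium, 5 central nervous system, 6 muscle, 10 heterochromatin, 4 Hox, 2 housekeeping and 1 ribosomal protein genes, and none of the 13 lists passed (adjusted permutation p from 0.696 to 1). Without having passed in any of these lists of peaks, the ratio was 1.88 for liver genes in the replicated list and 0.688 in replicate 1, 0.724 and 1.3 for central nervous system genes, and 0.585 and 1.12 for heterochromatin genes. For pluripotency genes it was 2.12 in the replicated list, 0.777 in replicate 1 and 0.937 in replicate 2.

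**Figure D4:**
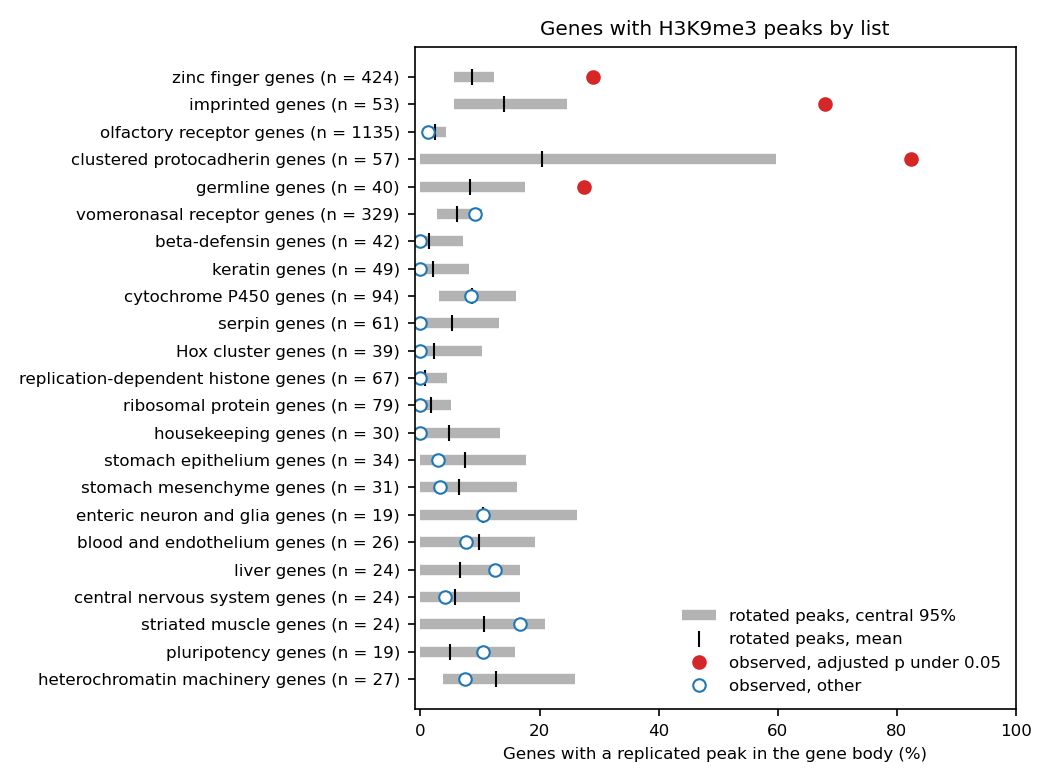
Share of genes (%) with a replicated peak in the gene body for each of the 23 lists (circles, filled where adjusted p is under 0.05), with the mean of rotated peaks (tick) and their central 95% (grey bar). The filled circles are the zinc finger (29.0%), imprinted (67.9%), clustered protocadherin (82.5%) and germline (27.5%) lists.

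Outside these lists, joining replicated peaks within 5 kb gave 7419 domains, of which 1145 held at least 2 peaks. After the Pcdhg domain the longest ran over the Ugt1a genes, which encode glucuronosyltransferases, and Mroh2a (chromosome 1, 88211451 to 88256878, 45.4 kb, 28 peaks). Its peaks were weak by fold, with a maximum of 3.56. The peaks there had −log10 p above other peaks of the same fold (median 12.3 against 3.84), unlike those of the Pcdhg domain (9.55 against 8.82). The Pcdha domain followed (37.6 kb), then 1 that overlapped Zfp982 (chromosome 4, 147507156 to 147539513, 32.4 kb, 17 peaks, 6 of them with −log10 p at least 1.5 times the median at their fold) and 1 without a protein-coding gene near the start of the chromosome 3 sequence (3000719 to 3032810, 32.1 kb, 21 peaks).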

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

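The tests of embryo sex on chromosome X, of both explanations for the number of peaks, and of local coverage at Ugt1a were chosen only after the results were seen. The design holds 1 group and so gives no biological explanation to set against these; the only one tested in this part was a lower number of zinc finger genes on chromosome X.

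Peaks on unplaced and unlocalized scaffolds were set aside from comparisons along the chromosomes, though not from counts of whole lists. They exceeded the limit of 3 that a count of 0 allows. There were 267 in replicate 1, 226 in replicate 2 and 195 in the replicated list. Over 5.25 Mb of scaffold sequence the replicated peaks covered 30514 bp per Mb, 18.7 times the 1628 bp per Mb of the chromosomes. The ratio was 9.51 in replicate 1 alone and 17.8 in replicate 2 alone. The median fold of the replicated scaffold peaks was 3.35 against 3.24 on the chromosomes, while their median −log10 p was 10.8 against 5.48. A high −log10 p for the fold was also seen at Ugt1a, described below, and its cause on scaffolds was not tested.

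Chromosome X carried 0.167 times the autosomal density of replicated bases, with 0.243 in replicate 1 and 0.169 in replicate 2. Less single-copy sequence on X was argued against as the whole cause, since the ratio per single-copy Mb was 0.203, below the bound of 0.5 set for it, and 0.295 in replicate 1. For fewer zinc finger genes on X, the ratio outside zinc finger gene bodies was 0.168, also below 0.5. These bodies held 6.91% of replicated peak bases, so leaving them out could not have brought the ratio to that bound. The values show only that peaks inside zinc finger gene bodies account for little of the low density. Lower read coverage of X in male embryos could not be weighed: no read counts were available here, the number of embryos of each sex is not stated, and the ratio of 0.167 alone cannot be told apart from an effect of copy number on peak calling.

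Replicate 1 had 2.46 times as many peaks as replicate 2, scaffold peaks included here and in the next ratio. Among peaks with −log10 q of at least 2 the ratio was 0.911, which is consistent with an excess of weak peaks in replicate 1 and does not say where these came from. The lists were also made with different further input files by the authors, and with each list made once, the ratio of 2.46 cannot be told apart from an effect of those files. Depth, which is unknown, stays open as well.

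The Ugt1a and Trpm8 genes on chromosome 1 (88211451 to 88310922) held 51 replicated peaks of low fold (median 2.56) that covered 60.1% of the segment, with 80 peaks in replicate 1 and 68 in replicate 2. Of these replicated peaks 96.1% had −log10 p at least 1.5 times the median of peaks of the same fold (within 5%), against 1.95% of all replicated peaks and 1.3% of those in the Pcdhg domain. Sequence repeated in the reference was argued against, since the median number of places at which a peak's 32-base words occurred was 1. Locally raised coverage in these libraries, such as extra copies relative to the reference would give, is a candidate explanation that the 96.1% fits, found and tested on the same peaks; a strain difference was not tested apart from it.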

How the results depend on the processing

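Alternatives chosen after the data were seen were rotation in single-copy sequence, the list rebuilt from pooled peaks overlapping both replicates (except for its count, which was planned), each replicate alone for chromosome density, peaks matched in number by p, and all those of the G and C share and of the named genes. Of 316 alternative values for 38 results, 299 were counted as the same. These passed in both settings in the same direction, passed in neither whatever their direction, or stayed within their spread or a count ratio of 1.5. Another 6 fell below the threshold, 4 rose past it, 7 moved and 0 reversed. A value that passed in neither setting could not be counted as reversed. Overlap of the replicates, the zinc finger last exon excess, the repeat-masked share, exon enrichment and the imprinted and protocadherin lists passed in every setting run. The replicated list shrank from 10010 peaks to 4727 with −log10 q of at least 2, because of the filter, and to 3697 when rebuilt, because overlap with both replicates was required. The promoter ratio fell to 1.12 in the pooled list. The intron ratio was 0.904 with the stricter q and 0.889 rebuilt, in both without passing; the intergenic ratio passed at 0.854 and 0.833 in these settings. With a replicate left out, ratios were 0.940 to 0.972 for intergenic sequence, which passed without replicate 1, 0.169 to 0.243 for chromosome X, 1.68 to 1.72 for chromosome 7 and 1.29 to 3.52 for germline genes, which did not pass without replicate 2. Germline genes also missed the threshold in the rebuilt list (3.86), as did zinc finger genes at promoters alone (1.53). Rho of the fold between replicates was 0.308 with reciprocal overlap and 0.302 for −log10 p. Apart from the filters named, the cause was not tested. Of 18 secondary lists over 10 alternatives, only the vomeronasal list passed, against length-matched lists, which do not keep gene clusters. The ratios of 12 secondary lists crossed 1 in some setting, none of them past the threshold there. Overlap and fold agreement have no value without 1 of the replicates. Depth is unknown, so which missing peaks reflect few reads cannot be judged.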

Other observations

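The comparisons of gene types, symbol families and single control regions in this part were chosen only after the data were seen; the prediction for the densest windows was written before its result. Among other annotated gene types, genes annotated as misc_RNA were covered more often than after rotation, 13 of 562 (2.31% against 0.25%, ratio 9.27, adjusted permutation p = 0.00749 over 15 gene types). Of these 13, 7 lay inside genes of the imprinted list: 3 in Gnas and Nespas (chromosome 2, near 174286608 and 174295071), and 1 each in Mest, Kcnq1ot1, Plagl1 and Meg3. Another 3 lay in Tug1, a long noncoding RNA gene on chromosome 11. The 13 are thus not separate sites, and most lay within longer genes. Processed pseudogenes (73 of 9940, ratio 1.71, adjusted permutation p = 0.00749), transcribed unprocessed pseudogenes (ratio 1.83), unprocessed pseudogenes (ratio 1.64), processed transcripts (ratio 1.29) and lincRNA genes (349 of 5854, ratio 1.16) passed too, whereas antisense genes (ratio 1.11, adjusted p = 0.310) and miRNA genes (4 of 2202, adjusted p = 1) did not. Although the bodies of H19 and Igf2 were free of replicated peaks, the imprinting control region annotated between them (chromosome 7, 142580248 to 142582833) held 2 replicated peaks, the higher of fold 3.38, with 1 peak in replicate 1 and 2 in replicate 2.

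Among 282 families of at least 10 protein-coding genes that share a symbol stem, only the Zfp stem passed the rotation test (119 of 394 genes, ratio 3.41, adjusted permutation p = 0.0282). Pcdhb genes, the protocadherins between the Pcdha and Pcdhg clusters, had peaks in 16 of 22 (ratio 39.0, adjusted permutation p = 0.0705), and Ceacam genes, which encode cell adhesion molecules, in 6 of 15 (ratio 6.14, adjusted p = 0.472). Pcdhga genes had peaks in 12 of 12 against 30.6% after rotation (ratio 3.27), and Pcdha genes in 12 of 12 against 43.2% (ratio 2.31), with adjusted permutation p = 1 for both. None of these 4 passed, and the Pcdhga and Pcdha families could not have, since 12 of 12 is the largest count possible.

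The 20 windows of 1 Mb with most bases under replicated peaks held 15.1% of those bases in 0.752% of the windows, while 25.5% of windows held no replicated peak. The next test used the same peaks as the zinc finger list, so it is not separate support for that list. Its random sets also do not keep neighbouring windows together. The hypothesis that clusters of zinc finger genes lie in the densest windows was tested against random sets of windows. The densest held a mean of 2.7 zinc finger genes against 0.160 in random sets (permutation p = 0.0001, the smallest the draws can give), which is consistent with it for part of the windows: 11 of the 20 held such genes and 9 held none. Those with zinc finger genes included the windows from 82000001 on chromosome 10 (54.7 kb covered), 12000001 on chromosome 7 (41.6 kb) and 147000001 on chromosome 4 (35.0 kb). Those without included windows with the protocadherins (107 kb), Ugt1a and Trpm8 (64.8 kb), Drg1 and Sfi1 on chromosome 11 (25.7 kb), secretoglobin genes (24.8 kb) and Ceacam and Psg genes (23 kb) on chromosome 7, and a stretch of chromosome 12 without genes annotated as protein-coding (20.4 kb). Immunoglobulin variable genes are annotated as a type apart, and genes of such types were not counted in the windows. Peaks with −log10 p at least 1.5 times the median at their fold, as at Ugt1a and Trpm8, also lay in other dense windows: 12 at Zfp981 and Zfp992 on chromosome 4 (146455118 to 146536611, median fold 3.66), 10 on chromosome 17 (13539944 to 13549749, median fold 2.88), 7 at Drg1 and Sfi1 (3154896 to 3200118, median fold 2.62, −log10 p up to 79.1), 7 and 6 in the window from 147000001 on chromosome 4, and 6 more at the start of that chromosome (3061774 to 3091118).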
